A study of Mus musculus with 6 samples.

How the data were processed

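RNA was extracted with TRIzol from pancreas of 9-week-old mice and made into mRNA libraries with a BGI kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the genome build mm10, without a role or order; the gene annotation and the strand setting are not given in the sources used here. A gene table of 16705 genes and a table of 54890 RefSeq protein-coding transcripts were used. The gene and transcript values tested are expected counts, deposited by the authors as read counts per library, and they are not all whole because reads shared between features are divided among them. The gene table also holds TPM values, per the file headers, scaled by the authors to transcript length and library size, and these served only for 1 alternative share of digestive enzyme transcripts. FPKM values per transcript were deposited by the authors too, per the file headers, and were not tested, since the expected counts keep the depth. Another 24 per-library columns and 16 columns of group means were not used.

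The mutant columns are named KI with the numbers 1 to 3. They were taken as K117E 1, 2 and 3, since they are the only columns that are not WT, K117E is the only other group and the numbers match; nothing in the labels spells this out. Replicate numbers were taken from the labels. Every library was compared with the others of its group by a chi-square test of their counts over genes, and all pairs differed by far more than sampling noise, so none was counted as a repeat of another.

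Of the 16705 gene identifiers, 16595 matched the RefSeq gene table of GRCm38.p6, from which gene coordinates were taken, and 110 did not, 97 of them unnamed gene models. Those 110 identifiers were kept in the counts. Coordinates of Hnf1a and its codon 117 come from GENCODE vM21 on GRCm38, the assembly that mm10 names, where the residue was checked to be lysine (K).

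Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR's quasi-likelihood test for K117E against WT without covariates, in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all features tested, with a threshold of 0.05 and no fold threshold. Transcripts were tested in the same way. DESeq2 1.42.0 served as the alternative tool. The design had been fixed for either normalized values or counts, and the count branch was used because both tables hold counts.

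Before the data were examined, 31 gene lists were fixed: genes known to depend on HNF1α, markers of the cell types a pancreas sample can hold, pathways and response genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry. Adjustment was over the 25 lists tested. The lists of B and plasma cell markers and mitochondrially encoded genes had 0 tested members, T and NK cell markers 1, Schwann cell and neuron markers 3, and intestinal epithelium markers and sex-linked genes 4 each, so they were not tested. List levels per library are means of log2(CPM + 1) over the listed genes in the table, or summed CPM. The share of counts in the digestive enzyme list and in the 10 most abundant genes was compared by a two-sided exact permutation test, which for 3 against 3 cannot go below 0.1. Shares carry 95% Wilson intervals, and a count of 0 is taken to allow up to 3 counts; these cover counting error only, since reads without molecular identifiers are not independent molecules.

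The genes named were chosen by a rule fixed in advance. It names Hnf1a, Hnf1b, Ins1, Ins2, Gcg, Sst, Slc2a2, Hnf4a, Cltrn and Pdx1 whatever their result, and for each described list up to 4 tested members with the smallest p. It also names up to 8 rises and 8 falls past the threshold with groups that do not overlap and a mean of at least 50 counts, of which there were 0. Other genes are said to be picked after their values were seen.

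The procedures were tested on simulated counts drawn with the means, depths and dispersions of these libraries, with 200 features changed 4-fold or 16-fold. Among 12246 simulated genes edgeR recovered 21% and 84% with 8 false calls, and DESeq2 51% and 92% with 54 false calls. Among 21478 simulated transcripts edgeR recovered 0% of either size, although the median estimated log2 changes were 2.33 and 4.02, because transcript counts vary so much between libraries. With a dispersion of 0.05 it recovered 97% and 100% with 7 false calls. A simulated list of 20 genes lowered by 1 log2 unit, among 25 lists, was called lower with 0 false lists; its genes were drawn independently, which real list members are not.

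The alternatives fixed in advance were no filter on low counts, a mean of at least 5 CPM, median-of-ratios size factors, equal totals without the digestive enzyme list, DESeq2, each library left out in turn, the replicate number as a block, an estimated correlation for lists, transcripts summed to genes, and the 50 most abundant genes. Those chosen after the data were seen were leaving out both K117E 3 and WT 3, limma's voom with sample quality weights, a term for libraries with Ddx3y counts, equal totals without the 110 unmatched identifiers, TPM in place of counts for the digestive share, and the estimated correlation in each of the other settings but voom.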

Results

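RNA from mouse pancreas at 9 weeks of age was sequenced in 3 wild-type (WT) libraries and 3 libraries from mice homozygous for the K117E substitution in HNF1α, a homeodomain transcription factor of liver, intestine, kidney and pancreas. Whole pancreas is mostly acinar tissue, which makes digestive enzymes, with ducts, islets of hormone-secreting cells, vessels and stroma. The libraries held 2066711, 2206984 and 3760475 gene-assigned counts in WT 1, 2 and 3, and 1785223, 4046294 and 6964864 in K117E 1, 2 and 3. The labels give each library a genotype, an age and a replicate number but do not say that a group's libraries came from separate animals. Summed CPM of 4 Y chromosome genes was 200, 169 and 18.0 in WT 1, 2 and 3, and 0, 190 and 9.55 in K117E. That argues against all 3 libraries of a group being repeats of 1 animal. P-values measure only the spread between these libraries, which may be technical in part. Levels are given as TMM-scaled CPM (counts scaled to library size), mean ± SD of n = 3 libraries per group. Fold changes are given as log2 of K117E over WT ± SE. That SE is the absolute log2 fold change divided by the square root of edgeR's F statistic.

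The first question was whether the substitution altered the transcript level of its own gene. Hnf1a (gene 21405) lies on the minus strand of chromosome 5 at 114948980 to 114971094 in GRCm38, and codon 117, which encodes the substituted lysine, occupies 114960191 to 114960193 in exon 2 of 10. Hnf1a stood at 30.8 ± 8.37 CPM in WT and 14.5 ± 12.1 CPM in K117E, and the libraries held 86, 79 and 55 counts in WT and 33, 82 and 7 in K117E. The log2 fold change was -1.13 ± 0.95, which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.744). Much of the difference came from K117E 3, without which it was -0.53 ± 0.44. Its paralog Hnf1b, a duct and progenitor factor, stood at 57.1 ± 6.72 CPM in WT and 21.2 ± 17.3 CPM in K117E, and all 3 K117E libraries lay below all 3 WT libraries. Hnf1b had a log2 fold change of -1.47 ± 0.89 and did not pass either (edgeR adjusted p = 0.675); without K117E 3 it was -0.87 ± 0.34. A point substitution leaves the transcript in place, so the Hnf1a level is no check of the genotype labels.

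The composition of the libraries was examined next, because a few acinar transcripts can take most of the counts of a pancreas library. The digestive enzyme transcripts took 5.93% (95% Wilson interval 5.90 to 5.96), 12.9% (12.9 to 13.0) and 38.5% (38.4 to 38.5) of the counts in WT 1, 2 and 3. In K117E 1, 2 and 3 the share was 3.58% (3.56 to 3.61), 2.27% (2.25 to 2.28) and 0.205% (0.202 to 0.208). The means were 19.1% ± 17.1 in WT and 2.02% ± 1.70 in K117E (SD, n = 3 each), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give (0.5 after Benjamini-Hochberg adjustment over the 5 measures compared). WT 3 accounted for much of the distance, since the difference of -17.1 percentage points became -7.42 without it. The 10 most abundant genes of each library took 25.9% ± 13.6 of the counts in WT and 22.2% ± 16.6 in K117E (exact permutation p = 0.8), a difference whose sign depended on single libraries, being 3.85 percentage points without WT 3 and 4.70 without K117E 3. Such intervals cover counting error only.

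K117E 3 stood apart from the other 5 libraries. It was the deepest library and held 12 insulin counts, against 518 to 25569 in the others, and its summed CPM was 0.0674 times that of the next lowest library for the digestive enzyme list and 0.00500 times for islet hormones. In summed CPM other pancreatic lists were less depleted, at 0.228 times for acinar factors and secretory machinery (762 CPM). The values were 0.433 for duct markers (391 CPM) and 0.518 for general endocrine genes (388 CPM). Members differed within these lists. Among duct markers Aqp1 stood at 103 CPM, but Tff2 at 3.86 and Spp1 at 0.203 CPM. Among acinar genes Serpini2 and Aqp12 were at 0.812 and 0.711 CPM. Among endocrine genes Gng12 stood at 33.5 CPM, while Chgb had 0 counts. The sums are thus no measure of the pancreatic tissue left. The fixed list of B and plasma cell markers summed to 1744 CPM in K117E 3 and to at most 15.7 CPM elsewhere, and the adipocyte markers to 2665 CPM against at most 189 CPM. Macrophage and dendritic cell markers summed to 4919 CPM against at most 683 CPM. The most abundant of these genes in that library, picked after their values were seen, were the antigen presentation chaperone Cd74 at 1301 CPM, the adipocyte carbonic anhydrase Car3 at 784 CPM and the immunoglobulin joining chain Jchain at 391 CPM. Spearman correlations across genes, which are not independent replicates, were 0.676 and 0.799 between K117E 3 and the other K117E libraries, 0.836 between K117E 1 and 2, and 0.855 to 0.907 among the WT libraries. No library pair agreed within sampling noise, and each library was counted as 1 sample.

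**Figure D1:**
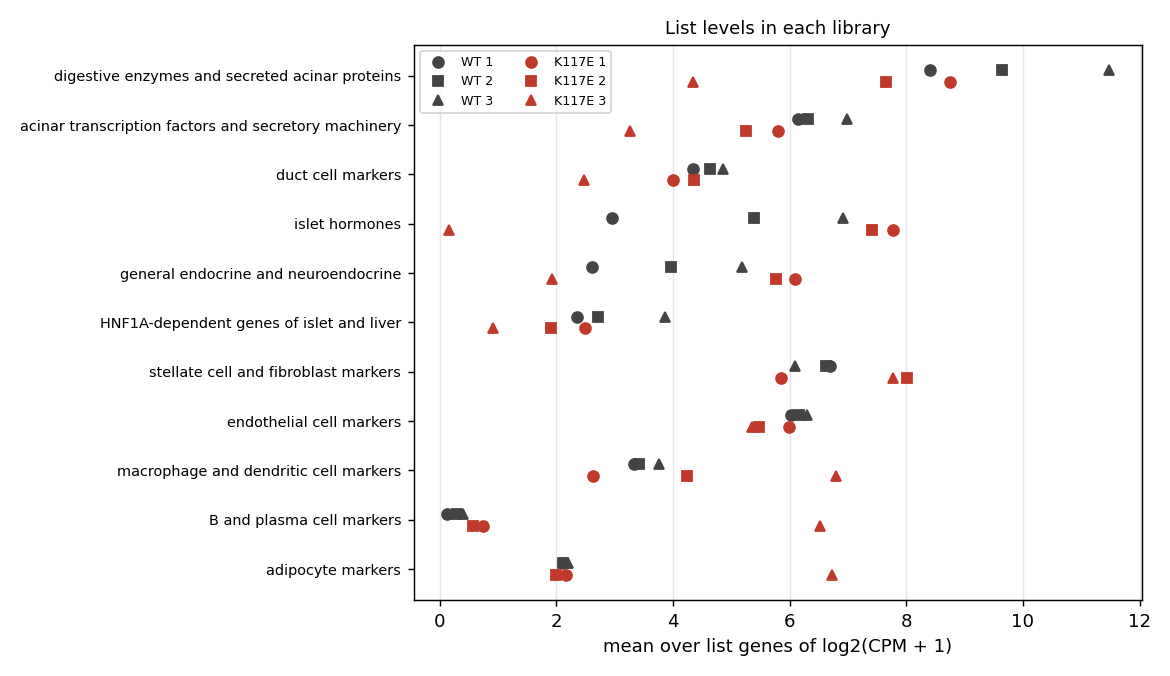
Mean log2(CPM + 1) over the genes of 11 fixed lists, 1 point per library (grey WT, red K117E; circles, squares and triangles are replicates 1, 2 and 3). K117E 3 lies lowest in the acinar, duct and islet lists and highest in the macrophage, B cell and adipocyte lists, at 6.52 against at most 0.74 for the B cell list.

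The central comparison asked which genes differ between K117E homozygous and WT pancreas. No single gene changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: of 12246 genes tested, 0 rose and 0 fell, with 988 at an unadjusted p under 0.05 and a smallest adjusted p of 0.556. DESeq2 called 59 of 12953 genes, 22 higher and 37 lower in K117E, of which 49 had an unadjusted edgeR p under 0.05. Groups did not overlap for 1757 genes (14.3%), where chance gives 10%. Without K117E 3, edgeR again called 0 of 11934 genes, with 930 at an unadjusted p under 0.05. In data simulated with the dispersions of these libraries, edgeR recovered 21% of 4-fold and 84% of 16-fold changes among 12246 genes, so most 4-fold changes were not recoverable at this spread. DESeq2 recovered 51% and 92% there, and also called 54 genes that had not been changed.

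The gene nearest to the threshold was Nr5a2 (gene 26424; chromosome 1, 136842562 to 136960448), a nuclear receptor that maintains acinar identity. Nr5a2 stood at 84.0 ± 10.3 CPM in WT and 8.04 ± 4.08 CPM in K117E and was lower in all 3 K117E libraries than in any WT library. Its log2 fold change was -3.43 ± 0.49, with an adjusted p of 0.556 by edgeR and 4.24e-06 by DESeq2. Across the 16 alternative settings its fold change stayed between -3.79 and -2.90, and its adjusted p ranged from 4.24e-06 to 0.949.

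Among the 25 fixed lists with at least 5 tested members, camera with the preset correlation of 0.01 called 11, 6 lower and 5 higher in K117E. With an estimated correlation it called 0, the smallest adjusted p being 0.515, and fry called 0 directional sets, with a smallest adjusted p of 0.286. The mixed test of fry, which allows members to differ in either direction, called 2 lists, immediate early genes and the circadian clock (adjusted p = 0.0389 each). Other divisions of the 6 libraries into 3 and 3 gave up to 14 lists, so the list calls below describe these libraries. Without K117E 3, camera called 12 lists, 7 lower and 5 higher, of which 8 were called in the same direction with all libraries. Over all genes tested, 0 members of any list rose or fell by edgeR.

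**Figure D2:**
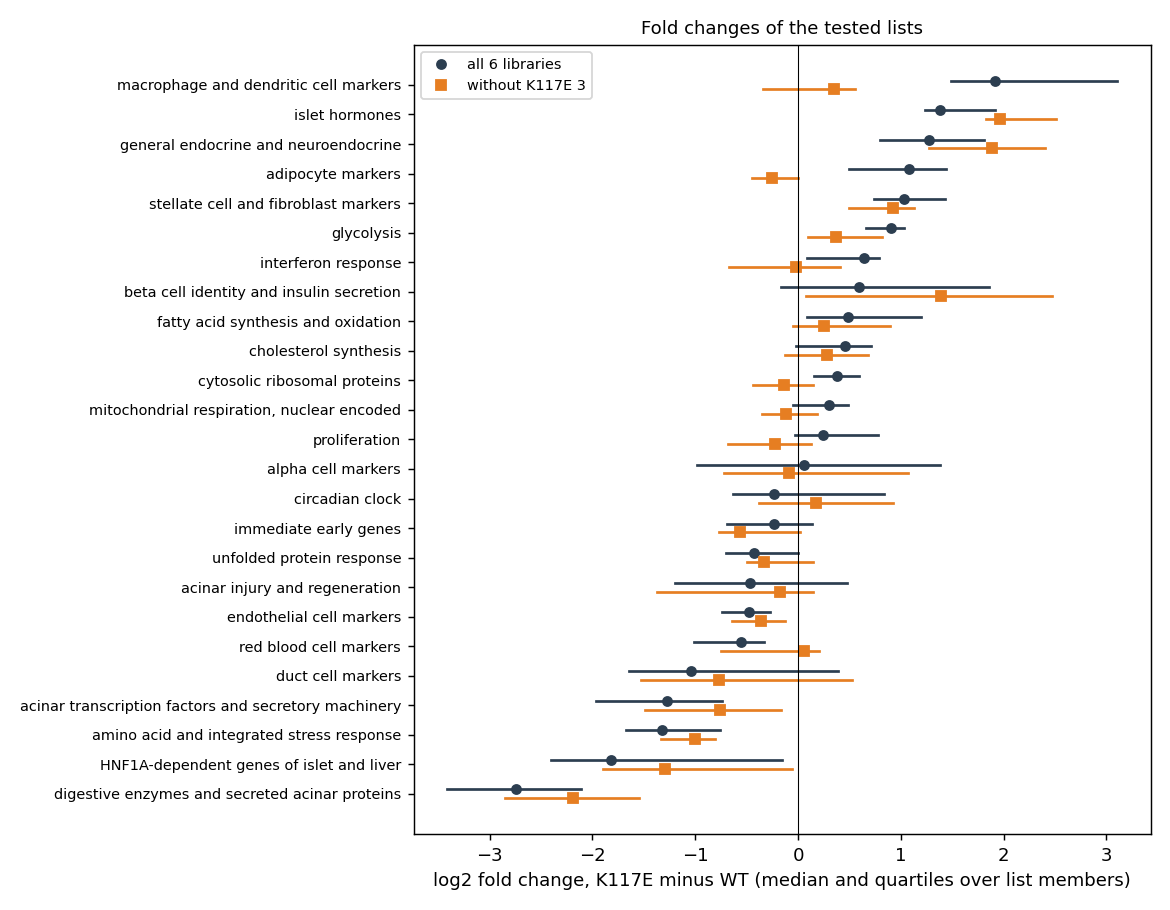
Median (points) and quartiles (lines) of the log2 fold change, K117E minus WT, over the tested members of each of the 25 lists, with all 6 libraries (dark circles) and without K117E 3 (orange squares). The digestive enzyme list has the lowest median with and without that library (-2.74 and -2.19), and the macrophage list moves from 1.92 to 0.35.

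Acinar transcripts lay lower in K117E. All 31 tested digestive enzymes and secreted acinar proteins had a negative fold change, with a median of -2.74 (camera adjusted p = 1.25e-15; adjusted p = 0.515 with an estimated correlation), and 0 passed when adjusted over the list alone. The proelastases Cela3a and Cela3b had log2 fold changes of -4.93 ± 1.13 and -3.73 ± 1.39, and Cela3b was at 5177 ± 6002 CPM in WT and 391 ± 369 CPM in K117E; without WT 3 the Cela3b fold change was -2.20. Trypsinogen family member Try10 had a log2 fold change of -2.90 ± 0.96. Counts of such families can be divided between near-identical copies, so their single values are uncertain. Among 20 acinar transcription factors and secretory genes, 17 had negative fold changes, with a median of -1.28 (camera adjusted p = 6.02e-08; adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 3 fell by edgeR: Nr5a2, the pancreatic serpin Serpini2 (-3.33 ± 0.91) and the acinar aquaporin Aqp12 (-3.34 ± 0.94). Without K117E 3, the lowest library in both lists, the medians were -2.19 for the digestive list and -0.76 for the factor list. The digestive median was -1.53 without WT 3 and -0.95 without both, and that of the factor list -2.26 without K117E 1 and -0.52 without both. K117E 1 (mean log2 level 8.75) lay above WT 1 (8.40) in the digestive list. In the factor list each K117E library (3.27 to 5.81) lay below each WT library (6.14 to 6.99).

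Genes of the amino acid and integrated stress response, induced by ATF4 when amino acids run short or protein folding is disturbed, also lay lower. Of 23 tested members 22 had negative fold changes, with a median of -1.32 (camera adjusted p = 5.20e-12; adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 4 fell by edgeR. The glutathione-degrading enzyme Chac1 had a log2 fold change of -3.05 ± 0.65 and the cystine transporter Slc7a11 of -3.19 ± 0.69. The neutral amino acid transporter Slc7a5 was at 320 ± 91.8 CPM in WT and 87.3 ± 46.9 CPM in K117E, and the proline synthesis enzyme Aldh18a1 at 142 ± 8.32 CPM and 57.2 ± 24.7 CPM. These 4, named for the smallest p of the list, were lower in each K117E library than in any WT library. That choice favors such a separation, and groups did not overlap for 14.3% of all genes tested. The list was lowest in K117E 3 (mean log2 level 4.11), and its median was -0.999 without K117E 3 and -0.88 without K117E 3 and WT 3. It moved with the acinar lists, which also lay lower. The unfolded protein response list had a median of -0.43 and was not called, though it was in other settings given below.

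**Figure D3:**
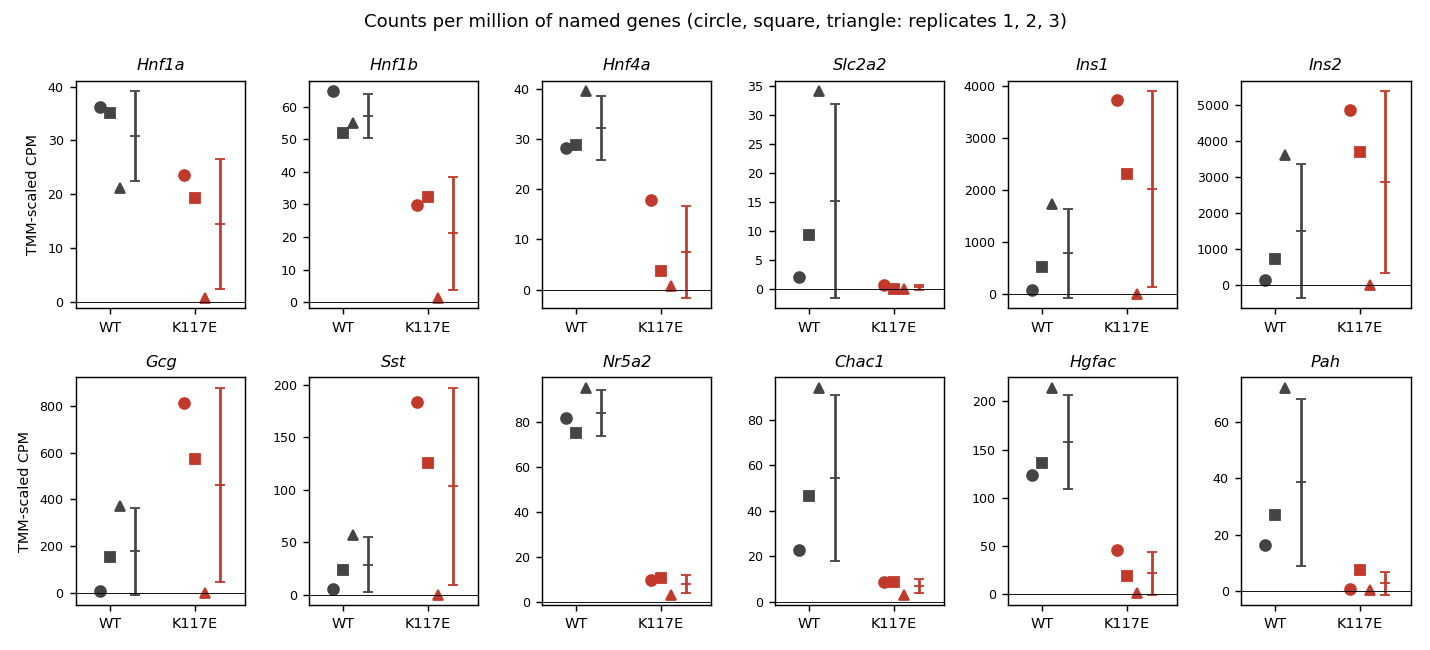
TMM-scaled CPM of 12 genes in each library on linear axes; circles, squares and triangles are replicates 1, 2 and 3, and the dash with bars is the mean ± SD of n = 3. Nr5a2 and Chac1 lie lower in all K117E libraries, and the hormone transcripts are near 0 in K117E 3 and above every WT library in K117E 1 and 2.

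Genes known to depend on HNF1α in islet and liver were fixed as a list before the data were examined. Of the 37 listed, 17 were tested and 13 of those had negative fold changes, with a median of -1.82 (camera adjusted p = 8.84e-06; adjusted p = 0.555 with an estimated correlation); 0 passed when adjusted over the list alone. Hepatocyte growth factor activator Hgfac was at 158 ± 48.9 CPM in WT and 22.0 ± 22.3 CPM in K117E. The phenylalanine hydroxylase gene Pah had a log2 fold change of -3.72 ± 1.16 (-6.85 without K117E 2), the forkhead factor Foxa3 of -3.12 ± 0.99 and the monocarboxylate transporter family gene Slc16a5 of -2.41 ± 0.81. Hnf4a, the nuclear receptor that forms a circuit with HNF1α, was at 32.2 ± 6.39 CPM in WT and 7.43 ± 9.14 CPM in K117E, with a log2 fold change of -2.28 ± 0.96 and an edgeR adjusted p of 0.601. Without K117E 1 the Hnf4a fold change was -3.93. The 6 libraries rank in this list as in the digestive enzyme list, so the list level moved with the acinar markers. The order was K117E 3 (mean log2 level 0.91), K117E 2 (1.91), WT 1 (2.35), K117E 1 (2.49), WT 2 (2.72) and WT 3 (3.86). That level averages 31 listed genes, of which 17 were tested. Hgfac, Pah, Foxa3 and Slc16a5, named for their small p, and Hnf4a were lower in each K117E library than in any WT library. It follows that K117E 1 lay below WT 1 for these genes, at 45.7 against 124 CPM for Hgfac and 17.8 against 28.2 CPM for Hnf4a. The choice by small p favors such a separation, so the 4 genes do not weigh against the order of the list level. Groups did not overlap for 14.3% of all genes tested. Of the tested members, 4 had positive fold changes. The list median was -1.29 without K117E 3, -1.07 without WT 3, -2.76 without K117E 1 and -0.53 without both K117E 3 and WT 3, where the call ended (camera adjusted p = 0.0866), a pair left out after the data were seen.

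Slc2a2, which encodes the GLUT2 glucose transporter of beta cells and hepatocytes, had 5, 21 and 89 counts in WT and 1, 0 and 0 in K117E. A count of 0 allows up to 0.704 CPM in K117E 2 and 0.305 CPM in K117E 3. The low-count filter removed Slc2a2 from the edgeR test. Slc2a2 did not pass by edgeR with no filter (log2 fold change -7.02, adjusted p = 0.583) or without K117E 3 (-5.93 ± 1.70, adjusted p = 0.413), while DESeq2 gave -7.27 with an adjusted p of 0.00498. These fitted sizes rest on libraries with 0 or 1 counts and are no bound. Cltrn, a beta cell membrane protein gene also known to depend on HNF1α, had 0, 0 and 18 counts in WT and 14, 19 and 0 in K117E (log2 fold change 0.92 ± 1.87, edgeR adjusted p = 0.899). Its direction turned without K117E 1 (-0.13), and without WT 3 the fitted change was 7.16, which rests on libraries with 0 counts and is no bound.

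Hormone transcripts of the islet varied widely within both groups. The insulin genes Ins1 and Ins2 were at 785 ± 859 and 1489 ± 1860 CPM in WT and at 2018 ± 1887 and 2839 ± 2525 CPM in K117E, with edgeR adjusted p of 0.842 and 0.897. Glucagon (Gcg) was at 177 ± 185 CPM in WT and 461 ± 417 CPM in K117E, and somatostatin (Sst) at 28.4 ± 26.2 and 103 ± 94.0 CPM, with edgeR adjusted p of 0.842 and 0.750. The log2 fold changes of Ins1, Ins2, Gcg and Sst were 1.36, 0.93, 1.38 and 1.84, the lowest with 1 library left out being 0.55, 0.30, 0.68 and 1.12 without K117E 1 and the highest 2.69, 2.70, 2.53 and 2.82 without WT 3. For all 4 hormones K117E 1 and 2 lay above every WT library, while K117E 3 held 4 Ins1, 8 Ins2, 0 Gcg and 0 Sst counts. The beta cell factor Pdx1 was at 29.4 ± 14.3 CPM in WT and 9.95 ± 7.99 CPM in K117E (edgeR adjusted p = 0.644), with a log2 fold change of -1.63, or -1.04 without K117E 3. Medians were 1.38 for the islet hormone list, 0.60 for beta cell identity and insulin secretion and 1.27 for general endocrine genes, and camera called none of them (adjusted p = 0.931, 0.842 and 0.131). Without K117E 3 these medians were 1.97, 1.39 and 1.89 and camera called all 3, with adjusted p of 5.59e-08, 1.62e-06 and 8.73e-13 (adjusted p = 0.392, 0.395 and 0.392 with an estimated correlation). Without WT 3 camera called the beta cell and endocrine lists (adjusted p = 0.0499 and 0.00695; adjusted p = 0.753 for both with an estimated correlation). The endocrine list was also called with all libraries scaled to equal totals without the digestive enzyme list (median 0.98, adjusted p = 0.0359; adjusted p = 0.734 with an estimated correlation). Adjusted over the list alone, 1 beta cell gene rose by edgeR, the islet factor Isl1. It was at 4.18 ± 1.01 CPM in WT and 21.1 ± 5.92 CPM in K117E, with groups that do not overlap. K117E 3, which held almost no hormone counts, had 141 Isl1 counts (14.3 CPM), so Isl1 there need not come from islet cells. The log2 fold change of Isl1 was 2.32 ± 0.53, and 2.55 ± 0.58 without K117E 3. The secretory granule protein gene Chgb had a log2 fold change of 2.62 ± 1.63 and the prohormone processing gene Cpe of 1.49 ± 0.71 (2.27 without WT 3).

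Duct and endothelial markers were called lower and stromal markers higher. The 19 tested duct markers had a median of -1.05 (camera adjusted p = 0.000487; adjusted p = 0.555 with an estimated correlation), with 12 negative and 7 positive, and included the water channel Aqp1 (-1.18 ± 0.30) and the membrane protein gene Prom1 (-2.36 ± 0.68). K117E 2 (mean log2 level 4.36) lay above WT 1 (4.34) in the duct list, whose median was -0.77 without K117E 3 and -0.27 without K117E 3 and WT 3. Of 14 endothelial markers 13 had negative fold changes, with a median of -0.47 (camera adjusted p = 0.000250; adjusted p = 0.515 with an estimated correlation), among them the angiopoietin receptor Tek (-1.38 ± 0.36) and endomucin, Emcn (-1.32 ± 0.38). Each K117E library (mean log2 level 5.36 to 5.99) lay below each WT library (6.03 to 6.30) in the endothelial list. The endothelial median was -0.29 without WT 3 and -0.83 without K117E 1. All 19 stellate cell and fibroblast markers had positive fold changes, with a median of 1.03 (camera adjusted p = 0.000415; adjusted p = 0.646 with an estimated correlation). Smooth muscle actin Acta2 was at 19.3 ± 3.31 CPM in WT and 77.7 ± 59.3 CPM in K117E (log2 fold change 2.01, or 1.21 without K117E 2), and transgelin, Tagln, at 19.3 ± 4.40 and 42.9 ± 11.8 CPM. K117E 1 was the lowest of the 6 libraries in the stromal list (mean log2 level 5.86, against 6.09 to 6.69 in WT), so the higher mean rests on K117E 2 (8.01) and K117E 3 (7.77). Without K117E 2 the stromal median was 0.56 (camera adjusted p = 0.0488). The stromal call ended without both K117E 3 and WT 3 (median 0.70, camera adjusted p = 0.151).

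Of the metabolic lists, glycolysis lay higher, with 15 of 17 members positive and a median of 0.90 (camera adjusted p = 4.81e-05; adjusted p = 0.515 with an estimated correlation). In mean log2 level of the list K117E 1 (4.36) lay within the WT range (3.99 to 4.49), below K117E 2 (4.94) and K117E 3 (5.39). In summed CPM the groups did not overlap (805 to 1019 in WT, 1141 to 2119 in K117E). Phosphoglycerate mutase Pgam1 had a log2 fold change of 1.27 ± 0.36, phosphofructokinase Pfkp was at 26.3 ± 10.3 and 68.1 ± 16.2 CPM, and pyruvate kinase Pkm at 164 ± 29.0 and 316 ± 48.8 CPM. Fatty acid synthesis and oxidation genes had a median of 0.49 (camera adjusted p = 0.0254; adjusted p = 0.515 with an estimated correlation), with Acadm, a mitochondrial beta-oxidation enzyme, at 1.32 ± 0.41. Without K117E 3 the glycolysis median was 0.37 and that of the fatty acid list 0.25, and the latter was no longer called (camera adjusted p = 0.0935). The fatty acid call also ended without WT 1, WT 3 or K117E 1, with medians of 0.33, 0.45 and 0.53.

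The 2 remaining called lists depended on single libraries. All 15 tested macrophage and dendritic cell markers had positive fold changes, with a median of 1.92 (camera adjusted p = 0.00850; adjusted p = 0.734 with an estimated correlation), the cathepsin gene Ctss being at 8.55 ± 1.07 CPM in WT and 80.9 ± 121 CPM in K117E (log2 fold change 3.26, or 0.35 without K117E 3). Without K117E 3 the median was 0.35, the direction of the test turned to lower and the list was not called (camera adjusted p = 0.688). Cytosolic ribosomal protein genes had a median of 0.38, with 26 of 32 positive (camera adjusted p = 0.00215; adjusted p = 0.819 with an estimated correlation), and without K117E 3 a median of -0.13 and no call (camera adjusted p = 0.519). That call also ended without WT 1 (median -0.00360) or WT 2 (median 0.20), and with a term for libraries with Ddx3y counts (median 0.16, camera adjusted p = 0.579), a term chosen after the data were seen. The ribosomal median was 1.15 without WT 3 and 0.62 without K117E 2, and 0.60 without both K117E 3 and WT 3 (camera adjusted p = 7.57e-09).

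The lists that camera did not call with all libraries had the following medians. Those of adipocyte markers, interferon response, cholesterol synthesis, nuclear-encoded mitochondrial respiration and proliferation were 1.08, 0.64, 0.46, 0.30 and 0.25. Those of red blood cell markers, acinar injury and regeneration, immediate early genes and the circadian clock were -0.55, -0.47, -0.23 and -0.23, with a mean of 0.11 for the clock list. Alpha cell markers had a median of 0.05, a mean of -0.05 and a test direction of lower. Adjusted over the list alone, edgeR gave 1 rise and 1 fall among clock genes (Bhlhe41, 3.13 ± 0.61, and Dbp, -2.05 ± 0.54). Alpha cell markers also had 1 of each (Mafb, 1.52 ± 0.42, and Slc7a2, -0.98 ± 0.34). Mafb was highest in K117E 3 (67.6 CPM), which had 0 Gcg counts, and its fold change without that library was 1.07 ± 0.43. Immediate early genes were called lower without K117E 3 (median -0.57, camera adjusted p = 0.0128; adjusted p = 0.392 with an estimated correlation). Single libraries moved other medians: acinar injury was at -0.20 without WT 1, -0.29 without K117E 1 and -0.18 without K117E 3, red blood cell markers at 0.02 without WT 3 and 0.05 without K117E 3, and immediate early genes at 0.05 without K117E 1.

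Some of these lists were called by camera in other settings, all with the preset correlation. With all 6 libraries and no filter on low counts, adipocyte markers were called higher (median 6.09, adjusted p = 0.00870), and red blood cell markers (-0.66, adjusted p = 0.0476) and the unfolded protein response (-0.44, adjusted p = 0.0380) lower. The adipocyte list was also called at a mean of 5 CPM (median 5.69, adjusted p = 0.0384), while without K117E 3 its median was -0.25. Equal totals without the digestive enzyme list gave calls for the unfolded protein response, lower (-0.58, adjusted p = 0.0211), and general endocrine genes, higher (0.98, adjusted p = 0.0359). Of the settings chosen after the data were seen, the Ddx3y term gave a call for the unfolded protein response (-0.59, adjusted p = 0.0121), and equal totals without the unmatched gene identifiers gave lower calls for red blood cell markers (-0.12, adjusted p = 0.0323) and acinar injury (-0.14, adjusted p = 0.0215). So did leaving out both K117E 3 and WT 3, also chosen after the data were seen. General endocrine genes (2.75, adjusted p = 1.96e-20) and the beta cell list (2.55, adjusted p = 1.06e-12) were called higher there. Islet hormones were also called higher (3.32, adjusted p = 2.09e-13), and immediate early genes lower (-0.51, adjusted p = 0.00935). Leaving out 1 library brought calls too. The unfolded protein response was called lower without WT 1 (-0.69, adjusted p = 0.000742) or K117E 1 (-0.77, adjusted p = 0.00237), and its median was -0.04 without WT 3 and -0.25 without K117E 2. Red blood cell markers were called lower without WT 2 (-0.70, adjusted p = 0.0405) or K117E 2 (-0.90, adjusted p = 0.00672). Interferon response was called higher without WT 1 (0.82, adjusted p = 0.0454) or K117E 1 (0.83, adjusted p = 0.00457), and adipocyte markers without K117E 2 (1.20, adjusted p = 0.0125). Without WT 3, cholesterol synthesis (0.71, adjusted p = 0.0160) and nuclear-encoded mitochondrial respiration (0.58, adjusted p = 0.00609) were called higher. The cholesterol median fell to 0.24 without WT 2 and 0.28 without K117E 3. With an estimated correlation 0 lists were called in any setting, the smallest adjusted p over the settings being 0.128.

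At the level of transcripts, the question was whether isoforms differed where gene totals did not. Of 21478 transcripts tested, 0 rose and 0 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 608 at an unadjusted p under 0.05 and a smallest adjusted p of 0.712, while DESeq2 called 169 higher and 125 lower. Hnf1a was represented by 1 transcript, with the same counts as the gene and a log2 fold change of -1.10 (edgeR adjusted p = 1.00). With the dispersions of these libraries, simulated 4-fold and 16-fold changes were recovered at 0% among 21478 transcripts, so the count of 0 carries no information on isoforms. With a dispersion of 0.05 the same procedure recovered 97% and 100%.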

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

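Leaving out K117E 3 and WT 3 together, the Ddx3y term, voom weights, totals without the 110 unmatched identifiers and the TPM share were tried only after the data were seen; the other alternatives were planned. The planned pseudocounts did not apply, because counts were tested. By edgeR the number of genes changed was 0 in all settings but 1: leaving out 1 library gave 0 to 1, the 1 being the gene model Gm13420 without K117E 1 (unadjusted p under 0.05 for 2205 genes there). DESeq2 gave 59, and 54 of the 54 of its calls that could be compared had the same sign in edgeR without K117E 3. That fit reuses the other libraries from which the calls were made, so the kept signs do not support them. Transcripts changed rose from 0 to 21 with no filter on low counts and to 294 by DESeq2, and stayed at 0 in the other settings where they were tested. Transcripts were not tested with voom weights, the Ddx3y term or totals without the unmatched identifiers. Called lists numbered 11 to 16 except with an estimated inter-gene correlation, where there were 0, in every other setting too (smallest adjusted p 0.128, tried after the data were seen); leaving out 1 library gave 11 to 14. Of the 11 called lists, 6 were called in every alternative but that one. The Hnf1a fold change ranged from -1.85 to -0.53 and never passed. Of 61 genes followed, 60 kept their direction throughout; Cltrn ranged from -0.13 to 7.16 when 1 library was left out. The difference in digestive share kept its sign, from -32.4 (TPM share) to -7.42 percentage points, while that of the 10 most abundant genes ran from -11.9 to 4.70 when 1 library was left out.

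The replicate number as a block gave 0 genes, 0 transcripts and 11 lists. Same-numbered libraries did not deviate together across genes (correlations of -0.20, 0.01 and -0.11). That gives no sign of a pairing, though the large differences between libraries could hide one.

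Test directions of lists turned as follows, given as medians of log2 fold changes, which can differ in sign from the test. Islet hormones turned with no filter (1.35), DESeq2 (1.39) and totals without the unmatched identifiers (1.93), and the beta cell list with the last (1.00). That scaling moved the median of all genes from 0.06 to 0.41, so its values read relative to 0.41. With the Ddx3y term, mitochondrial respiration (0.10) and proliferation (0.0896) turned, and the ribosomal call ended (0.16). Without both K117E 3 and WT 3 the medians were 0.31 for macrophages, 0.51 for red blood cells, 0.23 for the unfolded protein response, -0.25 for interferon, -0.46 for adipocytes, -0.0668 for proliferation, -0.36 for alpha cells and 0.15 for the clock. Leaving out 1 library gave 0.35 to 2.49 for macrophages, 0.75 to 2.27 for endocrine genes, -0.11 to 0.58 for mitochondrial respiration, -0.0214 to 0.83 for interferon, -0.25 to 1.35 for adipocytes, -0.23 to 0.75 for proliferation, -0.29 to 0.80 for alpha cells, -0.0784 to 2.102 for the beta cell list, -0.45 to 0.17 for the clock and 0.68 to 2.70 for islet hormones. Apart from the settings that drop libraries, the cause was not tested. Depth limits low genes: 1 count was worth most in K117E 1, where 3 counts are 2.14 CPM.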

Other observations

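All tests of explanations below were chosen after the results they bear on had been seen, except the splits of the libraries, which were planned.

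Libraries of both groups differed in transcripts of the Y chromosome, which the labels do not account for, since they give no sex. Ddx3y had 139, 124 and 0 counts in WT 1, 2 and 3 and 0, 235 and 0 in K117E 1, 2 and 3, and Kdm5d had 139, 86 and 0 and then 0, 221 and 0. The other 2 listed genes in the table had counts in WT 3 and K117E 3 too: Uty had 93, 103 and 20 in WT and 0, 193 and 42 in K117E, and Eif2s3y had 105, 68 and 27 and then 0, 161 and 52. Only K117E 1 had 0 counts of all 4. A gene model outside the GRCm38.p6 gene table, LOC118568705, took 18.6% (95% Wilson interval 18.5 to 18.7) of all counts in K117E 1 and 9.71% (9.68 to 9.73) in K117E 2, against 1.15% to 4.17% in WT and 0.347% in K117E 3. Together the 110 such identifiers took 17.6% ± 16.2 of the counts in K117E and 6.36% ± 3.20 in WT (SD, n = 3 each; exact permutation p = 0.4). K117E 1 stood apart in this share, at 33.6%, against 18.2% in K117E 2 and 1.12% in K117E 3. In WT 1, 2 and 3 it was 7.87%, 8.53% and 2.69%. The DESeq2 calls included 2 overlapping genes that moved in opposite directions, Trpc2 (log2 fold change 7.61) and Xntrpc (-8.20), picked after their values were seen. Their reads can be assigned to either, so both values are uncertain.

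For the groups as a whole, all 10 splits of the 6 libraries into 3 and 3 gave as many genes and transcripts as the real one, since each gave 0 of both by edgeR (988 genes and 608 transcripts at an unadjusted p under 0.05 in the real split, against up to 1204 and 782 in the others, both in the split of WT 1, K117E 2 and K117E 3 from the rest). Camera called 11 lists in the real split and 14 in the highest of the others, and 7 of the 10 splits gave at least 11. With 10 splits no share under 0.1 can be reached. That splits of any kind call many lists points to members of a list moving together between libraries.

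K117E 3 held few digestive enzyme and islet hormone transcripts (0.0674 and 0.00500 times the next lowest library). In summed CPM it held acinar factors at 0.228, duct markers at 0.433 and general endocrine genes at 0.518 times. Some members of these lists, such as Tff2 and Chgb, were lower still there. Shallow sequencing is argued against, since the total count of K117E 3 was 1.72 times that of the next deepest library. An effect of the genotype alike in each K117E library is argued against for the islet part, because the lower of K117E 1 and 2 held 1.17 times the islet hormone CPM of the highest WT library. RNA of adipose and lymphoid tissue in place of much of the pancreatic RNA may account for it. For this, 4 fixed lists (adipocyte, B and plasma cell, T and NK cell, macrophage) were picked after K117E 3 had been seen, which favors an excess. The smallest excess over the highest other library was 7.20-fold, and 61 of their 62 genes were highest in K117E 3. In some other library 10 counts were reached by 6 of 13 adipocyte and 19 of 20 macrophage genes. Only 3 of 14 B and plasma cell and 3 of 15 T and NK cell genes did so. The share of all genes highest in K117E 3, the deepest library, was not computed. A change of tissue in that 1 sample, or an exchanged sample, stays open and was not tested.

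The digestive enzyme list was lower in K117E, by 2.93 in mean log2 level. Whether K117E 3 alone is the source cannot be told apart from a difference in the group, since without it the difference was -1.64 with a standard error of 1.22. An acinar share that varies between samples of either genotype could account for the pattern in mean log2 level. The WT libraries alone spanned 3.07, and K117E 1 (8.75) lay above WT 1 (8.40). In the share of counts the groups did not overlap, at 5.93% or more in WT and 3.58% or less in K117E. Nor did they overlap in the acinar factor list (mean log2 level 6.14 to 6.99 in WT, 3.27 to 5.81 in K117E). The genotype stays open as well, as do differences in dissection, which no label records.

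Slc2a2 was almost absent from K117E 1 and 2 although their insulin transcripts were abundant. Per 1000 insulin counts the WT libraries held 9.65, 7.44 and 6.38 Slc2a2 counts, whereas K117E 1 held 0.0832 (exact 95% interval 0.00211 to 0.464) and K117E 2 held 0. Fewer beta cells are argued against, with exact limits that cover counting error only and not the spread between libraries. The upper limit of the Slc2a2 count in K117E 1 and 2 was 0.0232 times that expected from the lowest WT rate per insulin count. Per digestive enzyme count that ratio was 0.877, and it passed 1 when the WT count was put at its own lower limit (2.70), so a level that follows acinar content stays open. A loss of Slc2a2 in K117E beta cells stays a hypothesis, which Slc2a2 counts from isolated islets of both genotypes would settle and no test here does. Cltrn, another gene known to depend on HNF1α, had 1.16 and 0.743 counts per 1000 insulin counts in K117E 1 and 2, against 1.29 in WT 3. WT 1 and WT 2 held 0 Cltrn counts beside 518 and 2822 insulin counts, with exact upper limits of 7.12 and 1.31 per 1000. The Cltrn comparison thus rests on 1 WT library.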
